A study of Lupinus micranthus with 18 samples.

How the data were processed

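Leaf RNA of 18 Lupinus micranthus samples was measured by sequencing. Per the labels, total RNA was extracted with Trizol and libraries followed standard Illumina protocols, and samples fall into 6 groups of 3 by seed origin (America or Iceland) and treatment (none, PEG drought for 24 h or for 72 h). The submitters' processing notes name bcl2fastq 2.0.1, cutadapt 1.18 and RSEM 1.3.1, without saying what each was used for. The assembler, the assembly and any annotation are not given in the sources used here, and neither is strand.

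The authors deposited 1 table with a count column and an FPKM column for each library, per the file headers. The deposited counts are whole numbers per unigene that sum to 9603068 to 12605500 per library. RSEM estimates need not be whole, so these counts may have been rounded, which no source states, and reads shared between near-identical unigenes may have been divided among them. The deposited FPKM values are the counts scaled by 1 length per unigene and by the library total: in 256 unigenes with high counts in every library the implied length differed by at most 0.022% between libraries. FPKM therefore held no further measurement and was not used in tests. The table lists 81470 unigenes, of which 5703 have 0 counts in all 18 libraries.

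The counts were used as deposited, in R 4.3.3. Unigenes were kept by edgeR's filterByExpr, which left 30895, and libraries were scaled by TMM. All 18 libraries entered 1 edgeR 4.0.16 quasi-likelihood fit of 6 group means with 12 residual degrees of freedom. The 11 comparisons were PEG against untreated at each time within each origin, 72 h against 24 h within each origin, Iceland against America under each treatment, and the difference between the origins' responses at each time. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The common biological coefficient of variation was 0.345. TMM factors averaged 0.895 and 0.877 in untreated America and Iceland leaves and between 1.02 and 1.10 under PEG. CPM values use TMM-scaled totals, and log2 CPM adds a prior count of 2. The design, the alternatives and the rule for named unigenes were fixed before the data were examined.

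The rule for named unigenes took, where the table pairs no identifier with a name, at most 2 that rose most and 2 that fell most in each PEG comparison against untreated leaves, each comparison of origins and each difference of responses. They had to pass the threshold, reach a mean of 5 CPM in at least 1 group compared and, for 2 groups, not overlap between groups, which chance gives for 10% of unigenes. Between 1511 and 13330 of the called unigenes per comparison met the last condition. Folds against a group with 0 counts were computed against 3 counts over that group and are lower bounds; with 1 to 3 counts the ratio is given with a 95% counting interval. A set of 30 gene lists had been written beforehand, but their match needs names, so the lists and the camera tests on them were not run. The 20 most abundant unigenes and the 4 equal classes of abundance were chosen after the table was seen, ranked on the mean over all libraries. Differences in library measures between PEG and untreated libraries were tested by exact permutation within origin, two-sided. An exact test of 3 libraries against 3 cannot give p below 0.1, so none was run on single unigenes.

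The fit was tested on simulated data for all 30895 unigenes with 200 changed. In the comparison of 24 h PEG with untreated America leaves, 8% of 2-fold and 57% of 4-fold changes were recovered, with 1 false call. In the difference of responses at 24 h, 0% of 2-fold and 32% of 4-fold changes were recovered, with 0 false calls. With so few unigenes changed the adjusted threshold is stricter than in comparisons with many calls, so these shares do not carry over to those. Replicate pairs differed by more than sampling noise (chi-square per unigene 6.76 to 80.3 over 18 pairs), so no library was counted as a duplicate. The labels give no batch.

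Alternatives were DESeq2 size factors in the same fit, no filter on low counts, limma-voom (limma 3.58.1), the DESeq2 1.42.0 Wald test, a fit to only the groups compared, a further minimum of 2-fold, a replicate block, and leaving out each library in turn. Refits on fewer libraries applied the filter on low counts anew, which changed the unigenes tested. Settings for a table with FPKM alone did not apply. Settings for library measures, and refits without untreated Iceland replicate 3 of comparisons that do not involve its group, were added after seeing the data.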

Results

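The series measured messenger RNA in leaves of Lupinus micranthus seedlings, a lupin of the legume family. Seedlings were raised from seeds of 2 origins, America and Iceland, and were left untreated or put under drought with polyethylene glycol (PEG), an osmolyte that lowers the water available to roots, for 24 h or 72 h. Each of the 6 combinations was sequenced in 3 libraries, 18 in all. The deposited table gave counts for 81470 unigenes, the assembled transcript units of a species used here without a reference genome. Library totals ranged from 9603068 to 12605500 counts, so that 3 counts, the upper limit that a count of 0 allows, corresponded to 0.223 to 0.352 CPM (counts scaled to a common library total after TMM) in a single library. Intervals and limits of this kind cover counting error only. The table carried unigene identifiers without names or functions, so results are given for groups of unigenes defined by abundance or response and for a few identifiers chosen by a rule. After a filter on low counts 30895 unigenes were tested. The labels do not say whether replicates were separate plants, and p-values measure the spread between these samples, which may be technical. Each origin has a single untreated group, for which the labels give no hours. Differences from untreated leaves, or between 24 h and 72 h, therefore cannot be told apart from effects of seedling age, harvest time or handling.

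Libraries separated by treatment and by origin. The first principal component of log2 CPM held 37.2% of the variance and parted untreated from PEG libraries, and the second held 19.3% and parted the origins. Replicate correlations of log2 CPM across unigenes ranged from 0.93 to 0.948 in untreated America leaves and from 0.96 to 0.971 in America leaves after 72 h. Untreated Iceland leaves had the widest range, 0.896 to 0.962, because replicate 3 correlated at 0.902 with the other untreated Iceland libraries and stood nearer to the PEG-treated Iceland libraries, at 0.856, than replicates 1 and 2 did, at 0.801 and 0.79. No pair of replicates agreed within sampling noise.

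**Figure D1:**
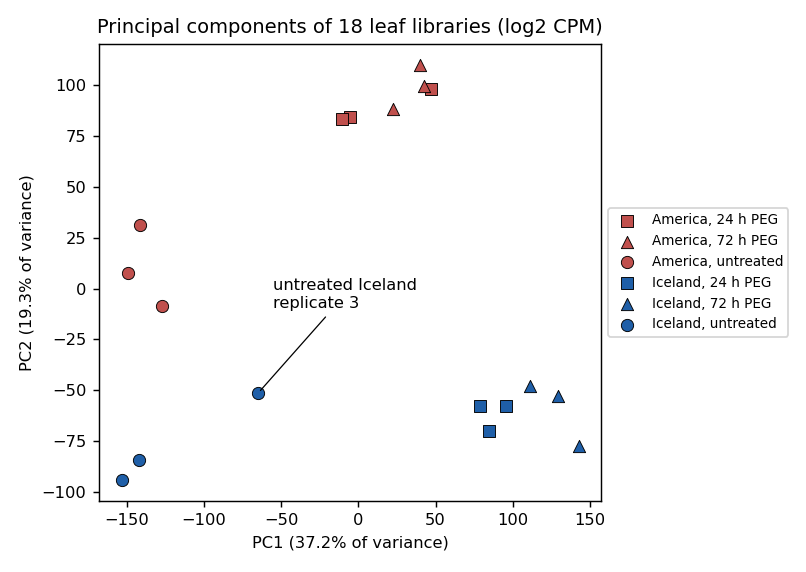
Principal components of the 18 leaf libraries, computed from log2 CPM of the tested unigenes. The horizontal axis is the first component (37.2% of the variance) and the vertical axis the second (19.3%); each point is 1 library, colour gives the seed origin and shape the treatment. Untreated Iceland replicate 3 lies between the other untreated Iceland libraries and the PEG-treated ones.

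The makeup of the leaf transcript pool differed between PEG and untreated leaves in both origins. The 20 most abundant unigenes, ranked by their mean share over all 18 libraries, held 14.9% ± 0.635 (SD, n = 3) of the counts in untreated America leaves, 8.61% ± 1.93 after 24 h and 7.16% ± 1.29 after 72 h. In Iceland leaves they held 15.2% ± 3.6, 10.2% ± 0.48 and 7.03% ± 0.266 (SD, n = 3 each). Across both origins the difference between PEG and untreated libraries was -6.83 points (two-sided exact permutation test within origin, p = 0.000142, the smallest its 7056 relabellings can give). Untreated Iceland replicate 3 held 11.1% in these unigenes, and without it the difference was -7.87 points. PEG leaves also had more detectable unigenes. At an equal depth of 9603068 counts per library, 43003 ± 1347 unigenes had at least 1 count in untreated America leaves, against 45777 ± 651 after 24 h and 46197 ± 283 after 72 h. Iceland leaves had 42970 ± 1104, 46758 ± 1084 and 48245 ± 326 (SD, n = 3 each). The mean difference between PEG and untreated libraries was 3758 unigenes (exact permutation test within origin, two-sided, p = 0.000142, again the smallest possible).

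**Figure D2:**
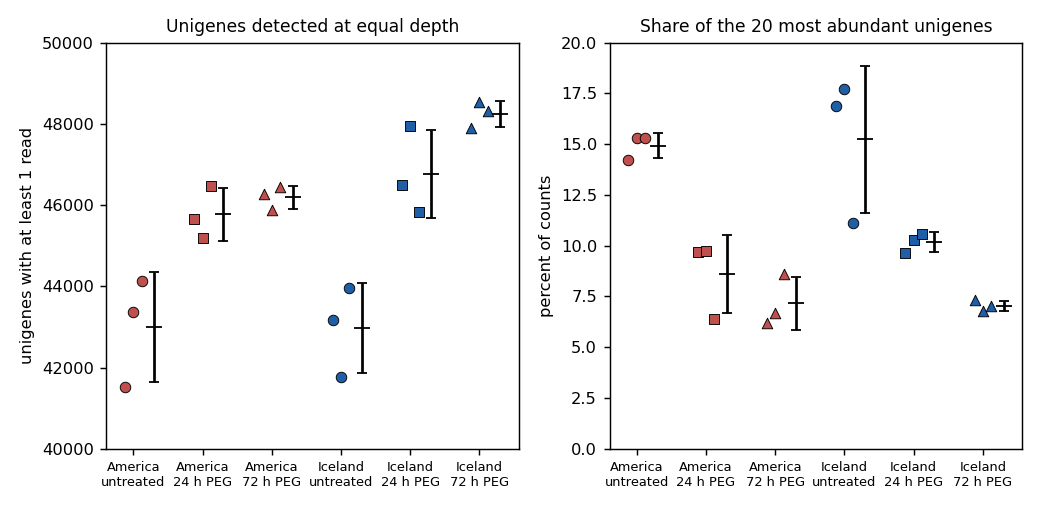
Left, unigenes with at least 1 count in each library at equal depth, on an axis that starts above 0. Right, the percent of counts in the 20 most abundant unigenes. Each point is 1 library, with the group mean and SD (n = 3) beside it. Every PEG library lies above every untreated library of the same origin on the left and below it on the right.

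The first set of comparisons asked how transcript levels under PEG drought differed from those of untreated leaves in America seedlings. After 24 h, 4945 unigenes were higher and 4676 lower than in untreated leaves, 9621 in all or 31.1% of those tested. Of these, 2984 rose and 3060 fell at least 2-fold. After 72 h, 5674 were higher and 5558 lower, 11232 in all, with 3613 and 3846 at least 2-fold. Among the 20 most abundant unigenes 13 fell and 2 rose after 24 h, with a median log2 fold change of -1.03, and 13 fell and 1 rose after 72 h, with a median of -1.47. Adjusted over these 20 alone, 14 fell and 2 rose after 24 h, and 13 fell and 1 rose after 72 h. Unigene0080662 fell from 0.741% ± 0.0504 of the counts to 0.145% ± 0.0355 after 24 h (log2 fold change -2.60 ± 0.24 SE, edgeR adjusted p = 3.49e-06), and Unigene0078298 rose from 0.125% ± 0.0331 to 0.396% ± 0.0487 (log2 fold change 1.42 ± 0.23 SE, edgeR adjusted p = 0.000317). These unigenes were chosen after their values were seen.

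Under the naming rule, the largest rises in America leaves came from transcripts with no counts in untreated leaves. At 24 h, Unigene0002894 reached 7.97 ± 2.09 CPM (SD, n = 3), at least 79.6-fold higher than the limit of 3 counts over the untreated group (edgeR adjusted p = 1.57e-05), and Unigene0011955 reached 23.8 ± 28 CPM, at least 233-fold higher (edgeR adjusted p = 0.00108, but 0.128 with limma-voom). At 72 h, Unigene0036237 reached 20.5 ± 13.5 CPM, at least 206-fold higher (edgeR adjusted p = 0.00206), and Unigene0054941 reached 19.0 ± 10.9 CPM, at least 190-fold higher (edgeR adjusted p = 0.00011). In the other direction, Unigene0074925 stood at 10.1 ± 2.73 CPM in untreated America leaves and had 0 counts at both times, at least 118-fold lower at 24 h and at least 127-fold lower at 72 h (edgeR adjusted p = 0.0156 and 0.0125). Unigene0075979 fell from 14.2 ± 8.04 CPM to 1 count over the 24 h libraries, a ratio of 496 with a counting interval of 88.6 to 19700, and to 0 at 72 h, at least 178-fold lower (edgeR adjusted p = 0.0184 and 0.0123). In Iceland leaves both had 0 counts untreated and at 24 h. At 72 h they stood there at 6.23 ± 7.7 CPM (Unigene0074925) and 6.57 ± 11.1 CPM (Unigene0075979). The falls of Unigene0074925 did not pass with DESeq2 (adjusted p = 0.106 and 0.0929), and that of Unigene0075979 at 24 h was lost without any 1 of the 24 h libraries (edgeR adjusted p up to 0.0782).

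Iceland seedlings were compared in the same way. After 24 h, 6079 unigenes were higher and 6379 lower, 12458 in all or 40.3% of those tested, with 4140 and 4428 at least 2-fold. After 72 h, 7225 were higher and 7099 lower, 14324 in all, with 5207 and 5150 at least 2-fold. Among the 20 most abundant unigenes 10 fell and 3 rose after 24 h (median log2 fold change -0.86), and 13 fell and 2 rose after 72 h (median -1.60). Adjusted over these 20 alone the numbers were 11 and 3, and 13 and 2. Unigene0080662 again fell, from 0.786% ± 0.168 to 0.127% ± 0.0123 after 24 h (log2 fold change -2.88 ± 0.24 SE, edgeR adjusted p = 1.29e-06). Without untreated Iceland replicate 3, 13899 and 15610 unigenes passed.

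At 72 h Unigene0061135 reached 203 ± 106 CPM (SD, n = 3) from 0 counts in untreated Iceland leaves, at least 1940-fold higher (edgeR adjusted p = 6.05e-07), while it had 1 count over the 3 America libraries at that time. At 24 h Unigene0066214 reached 31.9 ± 14.5 CPM, at least 297-fold higher (edgeR adjusted p = 0.000486), and had 0 counts in all 9 America libraries. Unigene0081382 reached 28.6 ± 12.1 CPM, at least 265-fold higher (edgeR adjusted p = 1.61e-06), and stood at 7.79 ± 2.49 CPM in America leaves at 24 h. Among the falls, Unigene0030012 went from 48.1 ± 18.6 CPM to 0 counts at 24 h, at least 525-fold lower (edgeR adjusted p = 5.53e-07), and Unigene0072091 from 11.5 ± 8.49 CPM to 0, at least 121-fold lower (edgeR adjusted p = 0.00935). At 72 h Unigene0021000 fell from 9.13 ± 7.48 CPM to 0 counts, at least 99.8-fold lower (edgeR adjusted p = 0.000172). The other named changes at 72 h were unstable. Unigene0076212, at 35.9 ± 53.2 CPM (at least 309-fold higher, edgeR adjusted p = 0.0315), lost its call in 5 of 12 refits, and Unigene0064682, down from 16.1 ± 27.7 CPM (at least 190-fold lower, edgeR adjusted p = 0.044), in 6 of 10, with adjusted p up to 0.146 and 0.697.

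**Figure D3:**
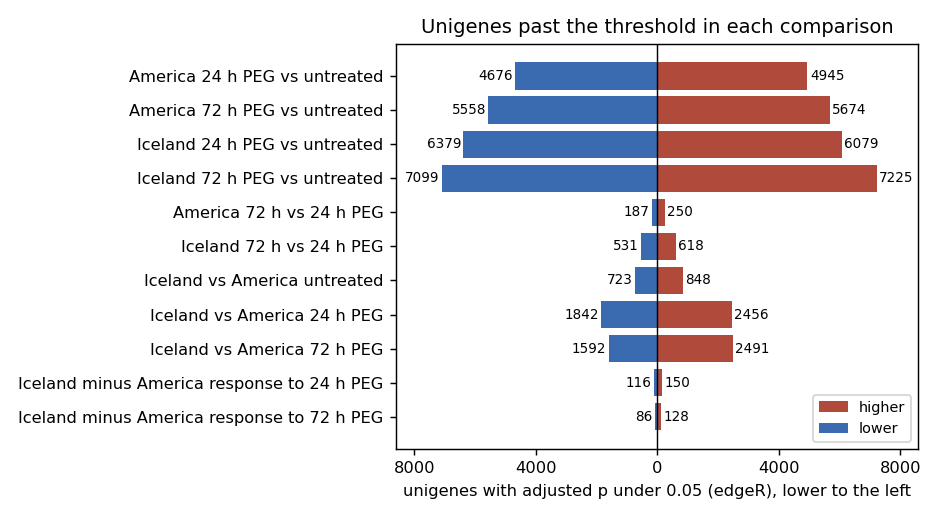
Number of unigenes past the threshold (edgeR, adjusted p under 0.05) in each of the 11 comparisons, higher to the right and lower to the left of 0. The PEG comparisons in Iceland hold the most, with 7225 higher and 7099 lower at 72 h, and the tests of a different response by origin the fewest.

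Between 24 h and 72 h fewer unigenes differed. In America leaves 250 were higher and 187 lower at 72 h, and in Iceland leaves 618 were higher and 531 lower (edgeR). None of the 20 most abundant unigenes changed between the times in America, and 3 fell in Iceland (7 adjusted over the list alone). The responses at both times overlapped. In America 4005 unigenes rose at both times and 3897 fell at both, against 908 and 841 from independent lists, and in Iceland 4897 rose and 5078 fell, against 1422 and 1466. Both times share their untreated libraries. In 20 simulations of unchanged groups against those controls, 0 unigenes passed at both times, as the adjusted threshold alone would give, the correlation of log2 fold changes was 0.524 against 0.860 observed in America and 0.516 against 0.796 in Iceland, and the covariance was 0.253 against 1.97 and 2.71. The 3 controls cannot be divided into parts of 2 libraries each, so part of the excess may come from them. The counts for 72 h against 24 h depended on the libraries used. They fell to 105 in America without 24 h replicate 2 and to 231 in Iceland without 72 h replicate 1, and to between 118 and 186 or between 290 and 591 without most of the others.

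The next question was how seedlings of the 2 origins differed under the same treatment. Without treatment, 848 unigenes were higher and 723 lower in Iceland than in America leaves, 1571 or 5.09% of those tested. At 24 h of PEG 2456 were higher and 1842 lower, 4298 in all, and at 72 h 2491 were higher and 1592 lower, 4083 in all. The 20 most abundant unigenes differed little: 2 were higher in Iceland at 24 h, and none passed without treatment or at 72 h by edgeR. Across all 3 treatments 147 unigenes were higher in Iceland and 152 lower, against 5.4 and 2.2 from independent lists. At both PEG times 1431 were higher and 501 lower, against 198 and 95. Fewer unigenes passed when most single libraries were left out. Without treatment the count lay between 641 and 861 for 5 of the 6 libraries and rose to 2580 without Iceland replicate 3. At 24 h it was as low as 2198 (without America replicate 2) and at 72 h 1595 (without Iceland replicate 2).

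In the unigenes named by the rule, 1 origin had no counts under the treatment compared. Without treatment, Unigene0009019 stood at 35.5 ± 7.5 CPM in Iceland, at least 357-fold higher than in America (edgeR adjusted p = 0.000297), and Unigene0024201 at 25.7 ± 8.75 CPM in America, with Iceland at least 246-fold lower (edgeR adjusted p = 0.000567). At 24 h, Unigene0052982 stood at 494 ± 97.6 CPM in Iceland, at least 5910-fold higher (edgeR adjusted p = 0.000305), against 0.485 ± 0.647 CPM in untreated Iceland leaves. Unigene0004940 stood at 68.0 ± 36.5 CPM, at least 798-fold higher (edgeR adjusted p = 0.0152). Lower in Iceland at 24 h were Unigene0036952 (at least 291-fold, from 28.1 ± 29.6 CPM in America) and Unigene0026475 (at least 322-fold, from 27.7 ± 34.1 CPM), with edgeR adjusted p of 0.00585 and 0.0146 but 0.0701 and 0.178 with limma-voom. At 72 h, Unigene0032025 was at least 157-fold lower in Iceland, from 13.6 ± 7.94 CPM in America (edgeR adjusted p = 0.00088), and had 4 counts over the untreated Iceland libraries. Unigene0020985 was at least 1010-fold higher, at 80.6 ± 69.7 CPM (edgeR adjusted p = 0.000742, but 0.134 with limma-voom), and Unigene0068689 at least 231-fold lower (edgeR adjusted p = 0.0147, lost in 2 of 12 refits). The remaining 3 were unstable. Unigene0008721 and Unigene0000880 without treatment (at least 199-fold higher and at least 111-fold lower, edgeR adjusted p = 0.0422 and 0.0284) and Unigene0050089 at 72 h (at least 896-fold higher, edgeR adjusted p = 0.028) each lost their call in 6 refits, with adjusted p up to 0.426, 0.266 and 0.283.

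Last, the responses to PEG were compared between origins. Most unigenes that passed in both moved in the same direction. At 24 h 3141 rose in both and 3601 fell in both, against 973 and 965 from independent lists, and 62 of 6804 moved in opposite directions. At 72 h 3991 rose and 4493 fell in both, against 1327 and 1277, and 119 of 8603 moved in opposite directions. These comparisons share no library. Across unigenes, which are not independent replicates, log2 fold changes correlated at r = 0.444 (Spearman's rho 0.533) at 24 h and r = 0.493 (rho 0.578) at 72 h, and with no filter on low counts at r = 0.200 and 0.225. Over the 4 PEG comparisons together 2560 unigenes rose in each and 3095 fell in each, against 42 and 40 from independent lists, a value that leaves out the untreated libraries shared within each origin.

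**Figure D4:**
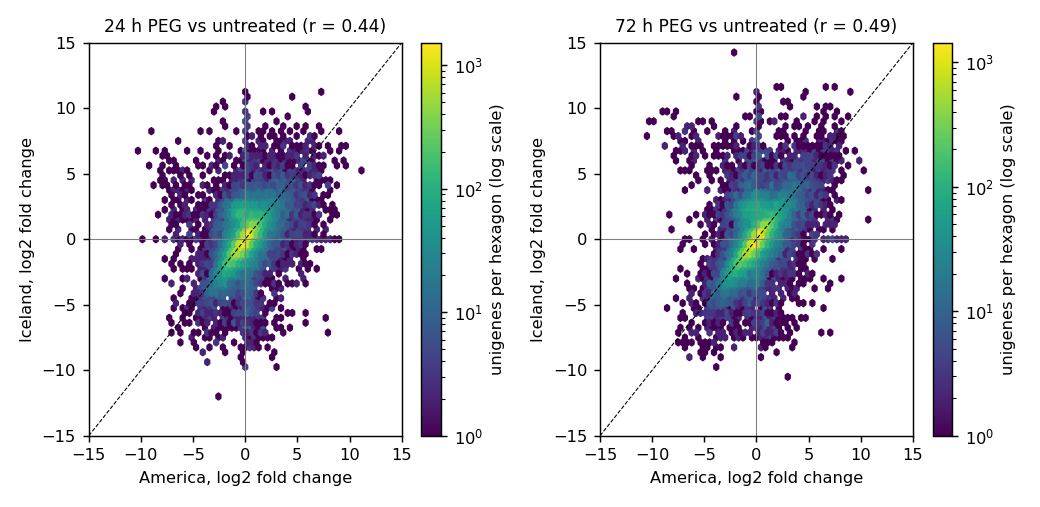
Log2 fold change against untreated leaves in America (horizontal) and Iceland (vertical) after 24 h (left) and 72 h (right) of PEG, over 30895 unigenes. Colour gives the number of unigenes per hexagon on a log scale, and the dashed line marks equal change. Pearson's r was 0.444 at 24 h and 0.493 at 72 h.

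A test of the difference itself called few unigenes, but it had little power. In simulated data at 24 h it recovered 0% of 2-fold and 32% of 4-fold changes. The DESeq2 Wald test called 1481 unigenes at 24 h and 1382 at 72 h, and limma-voom 69 and 15. Unigenes that did not pass are therefore not shown to respond alike. The response differed by origin in 266 unigenes at 24 h, more positive in Iceland in 150 and more negative in 116, and in 214 at 72 h, 128 and 86 (edgeR). Of the 266, 86 rose and 48 fell in Iceland without passing in America, 21 rose and 17 fell in America without passing in Iceland, and 46 passed in opposite directions. Of the 214 the numbers were 72, 24, 27, 9 and 55. Unigene0067379 fell in Iceland from 5.28 ± 1.63 CPM to 0 counts at 24 h and stood at 6 ± 1.22 and 3.93 ± 1.3 CPM in America (edgeR adjusted p = 0.0125), and kept its call in all 18 refits. Unigene0010407 rose in Iceland from 0 counts to 9.40 ± 3.64 CPM and in America from 0.506 ± 0.208 to 1.86 ± 0.534 CPM (edgeR adjusted p = 0.0091, lost in 2 of 18 refits). Both counts depended on the libraries used: without untreated Iceland replicate 3 they were 952 and 737, and without untreated America replicate 2 they were 29 and 6.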

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

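The tests of exchanged labels, of unigenes above every other library and of scaling were chosen only after the result was seen, and so were the limits placed below on the tests of allele contigs and of another organism. The pattern in unigenes of low abundance was taken up last, after the counts by abundance and the outcomes of the other tests were known.

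The response to PEG differed between origins, by a test of the difference itself, in 266 unigenes at 24 h and 214 at 72 h. Of 50 divisions of the libraries by origin, 5 gave at least as many at each time, the real one included, with highest other counts of 1994 and 1319. The other 4 at each time kept the PEG libraries parted by origin and exchanged 1 pair of untreated libraries. In the highest, all PEG labels were reversed. In such divisions a difference between origins that is the same under every treatment no longer cancels and enters the tested difference. They do not show what chance gives without a different response. The test therefore cannot decide on chance, which is not excluded at 0.05. Unigenes named by the rule had fitted log2 differences of responses of 12.58 (Unigene0000880), 7.83 (Unigene0010407), -9.39 (Unigene0030012) and -8.26 (Unigene0067379) at 24 h. At 72 h they were 16.84 (Unigene0067652), 16.35 (Unigene0061135), -10.28 (Unigene0003711) and -7.73 (Unigene0011604). Where a group had few or no counts these values depend on the prior count and are no bounds. Except for Unigene0067379, each lost its call in between 2 and 13 of 18 refits.

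For each of the 9 comparisons of 3 libraries with 3 the real division gave the highest count, 1 of 10, which is too few divisions for a share under 0.05. The real and highest other counts were 9621 and 1, 11232 and 0 for America at 24 h and 72 h against untreated, and 12458 and 105, 14324 and 1 for Iceland. For 72 h against 24 h they were 437 and 1 in America and 1149 and 9 in Iceland. For Iceland against America they were 1571 and 312 without treatment, 4298 and 0 at 24 h, and 4083 and 1 at 72 h. Each division estimated its own spread. A division that mixes the groups moves a real difference into that spread, which lowers its count. The other counts therefore do not show what chance gives where no difference exists.

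Untreated Iceland replicate 3 lay between the other untreated and the PEG-treated Iceland libraries. An exchange of labels with a PEG-treated Iceland library would leave a partner out of place, and 0 of the 6 were closer to untreated replicates 1 and 2 than to their own group. Admixture from PEG-treated Iceland material alone would give the same mixing share in every unigene. The median share was 0.13 (95% bootstrap interval 0.119 to 0.147) in 1088 PEG-induced unigenes. In 1157 PEG-repressed unigenes it was 0.593 (0.57 to 0.616), a difference of -0.462. Shares were taken against the mean of all PEG-treated Iceland libraries, so a single source library was not tried. Admixture from the other libraries also cannot account for 39 unigenes over 4 times above the highest of the other 17, led by Unigene0022506 at 4060 CPM against 839 (chosen after its values were seen). A partial stress or a different state of that plant may remain, alone or with a smaller admixture, as may a source outside these libraries. None of these was tested.

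More unigenes differed between origins under PEG than without treatment. Without untreated Iceland replicate 3 the 24 h count was still 2.1 times the untreated one (5416 against 2580). The untreated comparison then had 1 library fewer than that at 24 h, which can itself lower its count. Leaving out 1 of the libraries compared at 24 h gave 2198 to 3156 there. The ratio therefore cannot decide whether spread added by untreated Iceland replicate 3 accounts for the pattern. Low levels in untreated leaves do not account for all of it. Among 15381 unigenes of at least 5 CPM in untreated libraries the ratio was 2.03 (1716 against 844). With sampling variance removed, the SD of origin log2 differences over 16268 unigenes of at least 5 CPM was 0.501 at 24 h and 0.536 at 72 h and 0 without treatment, where the observed variance was below the sampling variance. Leaving out 1 library gave SDs of 0.257 (without Iceland 24 h replicate 2) to 0.602 at 24 h, 0.342 (without Iceland 72 h replicate 1) to 0.634 at 72 h and 0 to 0.135 without treatment, and the untreated SD was the lowest in every such fit. An SD of 0 is a floor of the method, since 844 unigenes of at least 5 CPM in untreated libraries passed between origins without treatment. The difference of 0.501 at 24 h therefore has no reliable size. That origins diverge under PEG remains a hypothesis, found and tested on the same data.

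Unigenes of low abundance were more often higher than lower in Iceland under PEG, and the balance changed with abundance. The filter on low counts and the ranking by abundance both used the libraries compared here. A unigene of low mean abundance can have passed the filter only through the group where it was high. How far this selection contributes to the balance was not tested. Of 4 equal classes counted from the lowest, the second also leaned higher at 24 h (643 higher and 419 lower). The third leaned lower at that time (323 and 596), and the highest was about even (456 and 460). In the lowest of 4 equal classes by mean abundance (7724 unigenes, median 0.753 CPM), 1034 were higher and 367 lower at 24 h and 1219 and 254 at 72 h, against 180 and 132 without treatment. Leaving out 1 of the 6 libraries compared lowered these counts, to between 374 and 730 higher and 134 and 242 lower at 24 h (374 and 193 without America replicate 2) and to between 452 and 1045 higher and 48 and 197 lower at 72 h (452 and 48 without Iceland replicate 2). With DESeq2 size factors 75.4% of the 24 h calls in this class were higher, against 73.8% with TMM. The choice between these scalings therefore does not account for the balance. Both gave close median log2 differences over all tested unigenes at 24 h (-0.0121 and -0.0542). A scaling error shared by both was not tested. For RNA of another organism present only on PEG-treated Iceland seedlings, the values in America leaves decide nothing. There 77.4% of the 1034 had 3 or more reads over the untreated libraries, but with a median of 6 reads these values lie near the floor. In untreated Iceland libraries 94.2% had 3 or more reads, and the set held 0.0456% ± 0.00126 of the counts (SD, n = 3). It held 0.181% ± 0.00827 at 24 h, where it was chosen for being higher, and 0.19% ± 0.052 at 72 h in Iceland leaves. Untreated America leaves, where this explanation allows no reads either, held 0.0228% ± 0.0118 (SD, n = 3). Part of the reads in untreated Iceland leaves may therefore have another source, which was not tested. The values in untreated Iceland leaves do not decide on presence under PEG only, and a lower amount in untreated leaves also stays open. Separate contigs for the alleles of the origins may also contribute. In the 90 of the 1034 with at least 1 CPM untreated, the median origin log2 difference was 4.18 without treatment against 2.94 at 72 h, which met the value that explanation needs, but the minimum selects on the untreated libraries then compared and leaves out most of the set, so the test decides nothing. Summed over the 1034, Iceland held 2.0 times the America share of counts without treatment and 7.8 times at 72 h, values computed after that test was seen, and an allele contig whose transcript is induced by PEG would give the same.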

How the results depend on the processing

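Settings for library measures, and refits without untreated Iceland replicate 3 of comparisons that do not involve its group, were chosen only after seeing the data. No named fold change and no correlation of responses reversed. The balance of higher and lower calls did turn over in places: the higher share for Iceland at 24 h went from 48.8% to 51.7% with DESeq2 size factors, for origins untreated from 54.0% to 47.9% with limma-voom, and for the difference of responses at 72 h from 59.8% to 43.8% without untreated America replicate 3. With DESeq2 size factors each count stayed within 1.5 times. Where counts moved the cause was not tested, except that a 2-fold minimum lowers counts by construction. Refits on fewer samples could also raise them: without untreated Iceland replicate 3, 2580 unigenes passed for origins untreated, against 1571. A 2-fold minimum left 6044 and 7459 unigenes for America at 24 h and 72 h, 266 and 751 for 72 h against 24 h in America and Iceland. DESeq2 gave 1486 and 2619 for the latter, 2766 for origins untreated, and 1481 and 1382 for the differences of responses at 24 h and 72 h. A fit to only the groups compared gave 204 for 72 h against 24 h in America, 344 and 2842 for origins untreated and at 24 h, and 16 and 41 for the differences of responses, which were 585 and 746 with no filter and 69 and 15 with limma-voom. The correlation of responses was 0.200 (24 h) and 0.225 (72 h) with no filter and 0.518 (24 h) with limma-voom.

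Leaving out 1 library gave 105 to 461 and 231 to 1215 for 72 h against 24 h in America and Iceland, 641 to 2580, 2198 to 3156 and 1595 to 4095 for origins untreated, at 24 h and at 72 h, and 29 to 952 and 5 to 737 for the differences of responses. The correlation ranged from 0.356 to 0.419 at 24 h and from 0.396 to 0.467 at 72 h, all below the 0.444 and 0.493 of the full fit. These refits applied the filter on low counts anew, so the unigenes compared changed along with the libraries. Of 474 refits of 36 named results with an adjusted p, 369 kept direction and threshold, 105 lost the threshold and 0 reversed.

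Replicate numbers did not pair the samples: pair correlations ran from -0.15 to 0.17. In 19 of 54 checks a library correlated best with its own number among the 3 libraries of the other group. Each library entered several of these checks. The replicate block gave 148 and 116 unigenes for the differences of responses, and within 1.5 times elsewhere. Gene list settings and those for FPKM alone were not run.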

Other observations

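Every test reported in this part was written before its result was seen, apart from the counts it starts from.

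A set of unigenes was nearly restricted to leaves of 1 origin. With at most 3 counts over the 9 libraries of the other origin and a mean of at least 10 counts in its own, 271 were found in Iceland and 56 in America leaves. Detected in all 9 libraries of their origin were 37 and 17. Of the 271, 134, 101 and 168 had counts in the untreated Iceland libraries, 177, 220 and 144 in those at 24 h and 219, 226 and 243 in those at 72 h, so the untreated and 24 h ranges overlapped. Of the 56, between 34 and 37 had counts in the untreated America libraries and between 40 and 52 in the PEG-treated ones. As a hypothesis, Iceland leaves may carry more transcripts that America leaves lack. Of 2000 divisions of the libraries by origin within treatment, drawn from 4000, 1 gave as large a difference as 215, the real one, and the highest other gave 209. This goes only against origin making no difference, and the margin is small. Divisions that mix origins put unigenes of 1 origin on both sides, which lowers the counts (largest sum in another division 259). The test therefore cannot decide whether the larger number in Iceland is chance. Absence of a gene, a diverged allele that maps elsewhere and a lack of expression were not told apart here.

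The larger number of unigenes detected under PEG was not a matter of read depth or of the most abundant transcripts alone. At equal depth the lowest PEG library lay 1058 unigenes above the highest untreated one in America and 1873 above it in Iceland, and without the 20 most abundant unigenes 85.2% of the difference was left.

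America 24 h replicate 3 held 48 unigenes over 4 times above the highest of the other 17 libraries, with 0.268% of its counts, and Iceland 72 h replicate 3 held 24, with 0.178%.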
